A study of Linum usitatissimum with 11 samples.

How the data were processed

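RNA from the outer stem tissues of 9 flax plants was measured on 11 one-colour arrays, per the labels. Groups and plant numbers were taken from the sample titles and the genotype label, which give 3 wild type and 6 lbf1 plants. The labels state that a pair of arrays came from one RNA sample in wild type plant 3 and in lbf1 plant 1, and each pair was averaged to 1 plant. Total RNA was extracted with TriReagent and labelled with the Agilent one-colour protocol, per the labels' protocols.

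The deposited scanner files give a spot intensity and a local background intensity at 532 nm, as median and mean of the pixels, on a linear scale up to 65535 units. Per the file headers, the arrays were scanned on a GenePix 4000B and quantified with GenePix Pro 6.0.1.22, with no normalization. The percent of saturated pixels per spot is also given per the file headers. The deposited spot flags mark each spot as found (0 or above), not found (-50) or marked bad (-100). Each array holds 45220 spots, of which 43455 are probes that are not controls, 43408 of them named with the letters Lus and a number and 47 with the word genolin. The columns for a gene hit and a description held 0 filled cells, so the probes stayed without gene names. The rest were 1264 positive control, 153 negative control and 348 ignored spots. The median of the negative controls lay 2 to 5 units above background on every array, and 33 to 109 probes per array were saturated in at least 50% of their pixels.

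The authors' deposited series table holds log2 values of the same arrays. Set against the scanner files, they equal log2 of the median intensity minus local background plus 1 constant per array, between -0.24 and 0.40, for all but 21 of the 318866 values, at a tolerance of 1e-06. Every column has a median of 9.79, and spots flagged as not found are blank. The scale and the centring are thus known, and with one colour there is no ratio whose direction could be open. How the probes were matched to genes is not given in the sources used here.

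The design fixed before the data were examined named Agilent processed signals. The files hold GenePix intensities, so the fallback written there was used. Background was corrected with normexp (offset 50) on the median intensities of all spots. Control spots and spots marked bad (306 over all arrays) were then left out and log2 values were quantile normalised between arrays. Saturated spots were kept. The offset and the background correction compress differences of dim probes, so fold changes of such probes are understated. All 43455 probes were tested, since the files hold no well-above-background flag of the planned kind. The found flag was used to describe probes. A plant counted as found where all of its arrays were.

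Genotypes were compared with limma 3.58.1 (lmFit and eBayes, two-sided, R 4.3.3) on the 9 plants, with no covariate. Adjustment was by Benjamini-Hochberg at an adjusted p of 0.05, and counts are also given for a log2 difference of at least 1. The random blocks used statmod 1.5.0. Probes were named by a rule fixed beforehand for probes without gene names: the 2 largest increases and the 2 largest decreases past both limits with no overlap between genotypes. The test was checked on simulated data for all 43455 probes with the means and residual SDs of the real ones. It recovered 34% of the probes changed by 0.5 log2 units, 66% at 1, 96% at 2 and 100% at 3, each from 50 probes, and called 5 of the 43255 unchanged probes. The changed probes were drawn from those with a wild type mean above the median, so dim probes are not covered. Far fewer probes changed than were called in the real data, and the noise was independent between plants with no slide effect. These rates therefore do not carry over directly to the real comparison. The 30 gene lists fixed beforehand, among them monolignol synthesis, laccases and class III peroxidases, could not be matched to unnamed probes and were not analysed here.

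Slide and scan day were taken from the file headers, and the 4 slides and 3 scan days are numbered in the order of scanning. All slides were scanned at the same detector gain. Slides and scan days were tested as a block, as a random block and within the day that holds both genotypes. Closeness of plants was compared with that of arrays. The closest pair of plants, lbf1 plants 3 and 4, had a median SD of 0.065 over the probes found on all arrays, against 0.051 and 0.038 between arrays of one plant, and all plants were kept as separate. Alternatives covered background correction, scaling, the deposited values, filters on dim probes, single arrays, leaving out each plant, blocks, the variance model, bad spots and the threshold.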

Results

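Transcript levels were measured in the peeled outer tissues of flax (Linum usitatissimum, cultivar Diane) stems at the vegetative stage. These tissues hold the bast fibres, long phloem fibres whose walls are rich in cellulose and poor in lignin in wild type flax. The lbf1 family was obtained by chemical mutagenesis with EMS (ethyl methanesulfonate), and its name stands for lignified bast fibres. RNA of 3 wild type plants and 6 lbf1 plants grown in the field was labelled with Cy3 and hybridised to one-colour arrays that carry 43455 non-control probes, 1 spot each. Wild type plant 3 and lbf1 plant 1 were each hybridised on 2 arrays, giving 11 arrays in all. Between 27073 and 29869 probes per array were found by the scanner software, or 62.3% to 68.7%. The median spot intensity was 211 to 388 units over a local background of 38 to 44 units. The precision of each comparison is limited by the number of plants, 3 and 6.

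The series asks which transcripts of the outer stem differ between lbf1 and wild type. The files pair no gene name or description with the probes. Differences are therefore given by groups of probes, and by the identifiers of the 2 largest increases and the 2 largest decreases.

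In lbf1, 1873 probes were higher and 2007 were lower than in wild type by 2-fold or more, at an adjusted p under 0.05 in limma. Without a limit on size, 14886 of the 43455 probes passed (34.3%), with 7035 higher and 7851 lower in lbf1. Of the 3880 probes past both limits, 3813 had no overlap between the 3 wild type and the 6 lbf1 plants. Over all probes, 33.3% had no such overlap, and chance gives 2.38%. Large changes were mostly increases. At 4-fold or more, 656 probes rose and 300 fell, at 8-fold 242 rose and 44 fell, and at 16-fold 104 rose and 9 fell. At 32-fold or more, 45 probes rose and 0 fell. In the 4-fold class the ratio of increases to decreases was 2.19. Over the other scalings it ranged from 1.68 with median centring to 12.1 with scaling on the E1A control spots of the array, and with plain background subtraction it was 1.56.

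The balance of higher and lower probes depended on the scaling, and the values above are relative to a common distribution of levels on all arrays. Scaling on the E1A control spots in place of quantile normalisation raised the median difference of all probes to 0.54 on the log2 scale. It called 19476 probes, of which 93.2% were higher in lbf1. Such a shift is shared by all probes of an array, while limma treats the noise of each probe as its own. These counts thus largely restate the shift and are not separate results per probe. Whether each labelling received an equal amount of the E1A control was not tested. The mean of these control spots on slide 2, which held 4 lbf1 plants and no wild type plant, was 10.78 on the log2 scale, against 11.30 on slide 1. Without the 4 plants of slide 2 the median difference under E1A scaling was again 0.54, with 82.4% of the called probes higher in lbf1. Between the plants of slide 1, the only slide with both genotypes, it was -0.03. With median centring the median difference of all probes was -0.16. With the authors' deposited values, 57.3% of the called probes were higher in lbf1, against 47.3% here. All 3880 probes kept their direction under E1A scaling, and so did the 3386 of them with a deposited value that could be tested. This was close to fixed in advance and is no check on the scaling. The probes were chosen on the same arrays for a log2 difference of at least 1, and E1A scaling moved the median difference by less than that.

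**Figure D1:**
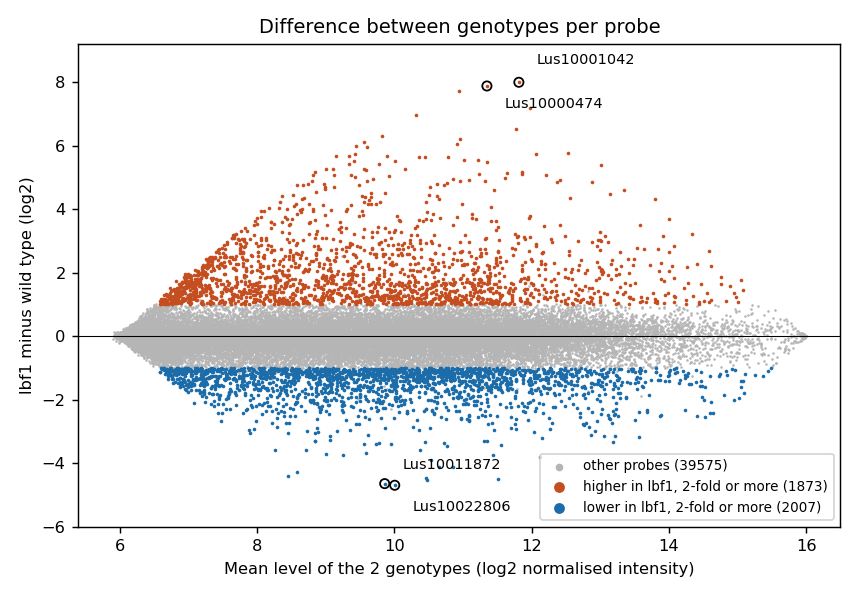
Each point is 1 of the 43455 probes, with the mean of the wild type and lbf1 levels on the x axis and lbf1 minus wild type on the y axis, both as log2 of quantile-normalised intensity. Orange and blue points are the 1873 higher and 2007 lower probes past both limits, the 4 named probes are circled, and the points above 5 on the y axis have no counterpart below -5.

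Probes Lus10001042 and Lus10000474 showed the largest fitted increases. The level of Lus10001042 was 15.81 ± 0.25 (SD, n = 6) in lbf1 and 7.82 ± 2.10 (SD, n = 3) in wild type on the log2 scale. The difference was 7.99 (SE 0.72), or 255-fold, with a limma adjusted p of 6.05e-05. The probe was saturated on 5 of the 7 lbf1 arrays and was not found in wild type plant 1, so the fold is a rough figure. Lus10000474 had a level of 15.29 ± 0.68 in lbf1 and 7.41 ± 1.66 in wild type, a difference of 7.88 (SE 0.67; limma adjusted p of 4.43e-05). It was found on 2 of the 4 wild type arrays, in full in only 1 of the 3 wild type plants, and on all 7 lbf1 arrays, 1 of them saturated. Saturation and levels near the floor both shorten such differences, so neither value is exact and the order of the 2 probes is not settled. With the authors' deposited values the differences were 7.53 for Lus10001042 and 7.75 for Lus10000474. Those values are blank for spots not found, so they leave out wild type plant 1 for Lus10001042. For Lus10000474 they rest on 2 of the 4 wild type arrays, so they are not on the same plants as the values above. In each of these probes wild type plant 2 had the highest wild type level, at 10.17 and 9.30. Without that plant the differences were 9.17 and 8.83, and without wild type plant 1 they were 7.15 and 7.27.

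Probes Lus10022806 and Lus10011872 showed the largest decreases. Lus10022806 had a level of 12.35 ± 0.48 (SD, n = 3) in wild type and 7.66 ± 0.75 (SD, n = 6) in lbf1, and it fell by 4.69 (SE 0.43; limma adjusted p of 6.67e-05), a 25.9-fold change. Lus10011872 stood at 12.18 ± 0.39 in wild type and 7.54 ± 0.58 in lbf1, and it fell by 4.64 (SE 0.34; limma adjusted p of 2.05e-05). Both were found on all 11 arrays. The rule that picked the 4 probes asked that every lbf1 plant lie on the same side of every wild type plant, so this holds for all of them by selection.

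**Figure D2:**
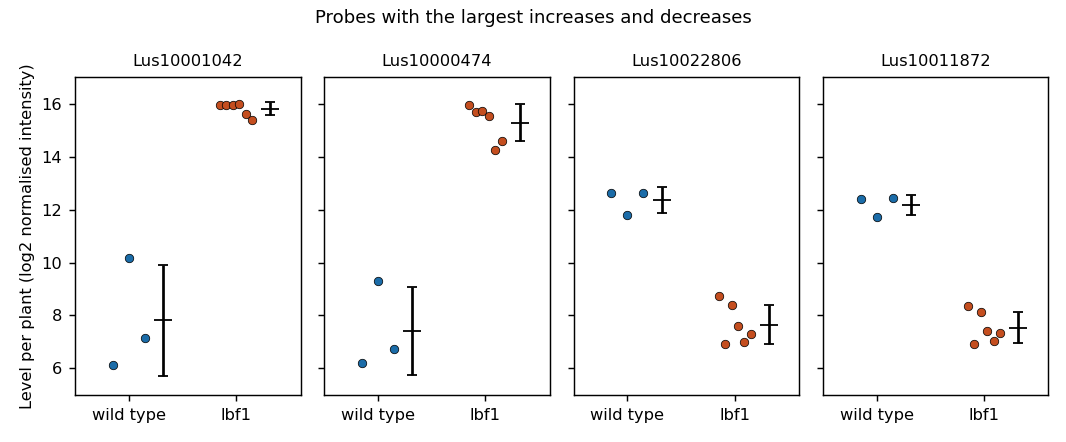
Points are single plants (3 wild type, 6 lbf1) and the y axis is log2 of quantile-normalised intensity, with the arrays of a plant averaged; bars beside the points are the mean and SD. Lus10001042 and Lus10000474 average 15.81 and 15.29 in lbf1, while Lus10022806 and Lus10011872 average 7.66 and 7.54 there.

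A group of 531 probes was found in all 6 lbf1 plants and on no wild type array. Of these, 515 were past the limma threshold, and for 380 of them the level in lbf1 was at least 2-fold higher. For 58 it was at least 8-fold higher, and the largest of these bounds was 51.1-fold. The opposite group, found in all 3 wild type plants and on no lbf1 array, held 100 probes. All 100 were past the threshold, 85 of them with a level at least 2-fold lower in lbf1 and 2 of them at least 8-fold lower. Each bound sets the mean of the genotype with signal against the lowest level of any found probe on the arrays without it, or against the probe's own level where that was higher. Both groups were picked by detection on the same arrays, so passing the limma threshold was close to fixed by the selection. The first group grew to 964 probes without wild type plant 3. The found flags are not normalised, and the arrays of wild type plants 1 and 2 had the lowest shares of probes found, 62.3% and 64.0%. On the lbf1 arrays the share was 65.3% to 68.7%. The groups also set unequal conditions, on 3 and on 6 plants, so their sizes are not directly comparable. How far detection accounts for the larger first group was not tested.

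Probes found on all 11 arrays numbered 25904, and 11886 of them (45.9%) were past the threshold. By 2-fold or more, 1279 of them were higher and 1673 lower in lbf1. The 7203 probes found on some arrays gave 594 higher and 334 lower at that size. Of the 10348 probes found on no array, 424 (4.10%) passed the threshold, and 0 of them reached 2-fold. The 47 probes with identifiers starting with genolin included 21 past the threshold, of which 2 were higher and 7 lower by 2-fold or more.

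The spread between plants was larger than that between arrays of one plant. The median SD over all probes was 0.046 between the arrays of wild type plant 3 and 0.038 between those of lbf1 plant 1, in log2 units. It was 0.11 between the 3 wild type plants and 0.14 between the 6 lbf1 plants. These are medians of SDs over 2, 3 and 6 values, which run lower the fewer the values, so they are not directly comparable. For SDs of 2 values each, over probes found on all arrays, the array pairs gave 0.051 and 0.038. On that measure wild type plant pairs gave 0.107 to 0.137 and lbf1 plant pairs 0.065 to 0.186. Both array pairs were on slide 1, while the plants of a genotype spanned slides. Correlations across probes, which are not independent replicates, were 0.997 between arrays of one plant. They ranged from 0.993 to 0.995 between wild type plants, from 0.983 to 0.996 between lbf1 plants and from 0.947 to 0.966 between the genotypes. The first principal component held 72.8% of the variance and separated the genotypes.

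Genotype and slide overlapped in part. Slide 1 held wild type plant 3 and lbf1 plant 1, slide 2 held lbf1 plants 2 to 5, slide 3 held lbf1 plant 6 and slide 4 held wild type plants 1 and 2. Slides 1 and 2 were scanned on the same day. With slide as a block, limma called 6342 probes, 3739 of them by 2-fold or more. Slide 1 alone informs that comparison, with 1 plant against 1, and the spread comes from the plants of slides 2 and 4, on 4 residual degrees of freedom. With scan day as a block it called 8498 probes. Within scan day 1, with wild type plant 3 against 5 lbf1 plants, it called 7762 probes, 3543 of them by 2-fold or more; the lone wild type plant is assumed there to vary like the lbf1 plants. With slide as a block, Lus10001042 and Lus10000474 differed by 8.82 and 9.22, and Lus10022806 and Lus10011872 by -3.89 and -4.06, the highest of the 4 limma adjusted p being 0.0255. Within scan day 1 these differences were 8.75, 8.69, -4.89 and -4.85.

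Slides were also compared within a genotype. Wild type plant 3 on slide 1 against the wild type plants of slide 4 gave 0 probes past the limma threshold and 3311 at an unadjusted p under 0.05. In lbf1, slide 1 against slide 2 gave 6 probes, with 5232 at an unadjusted p under 0.05, and slide 3 against slide 2 gave 107, with 3653. Each of these contrasts has a lone plant on 1 side, assumed to vary like the others, and rests on 4 residual degrees of freedom. From the plants of slides 2, 3 and 4, 3681 probes differed between the genotypes by 2-fold or more, and 3649 of these (99.1%) differed in the same direction between lbf1 plant 1 and wild type plant 3 on slide 1.

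Each plant was also placed on a scale from the mean of wild type, at 0, to the mean of lbf1, at 1, with the scale built without that plant. Wild type plants lay at 0.023 ± 0.037 (SD, n = 3) and lbf1 plants at 0.984 ± 0.093 (SD, n = 6). The lowest lbf1 position was that of plant 6, at 0.830, and the highest was that of plant 1, at 1.08.

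**Figure D3:**
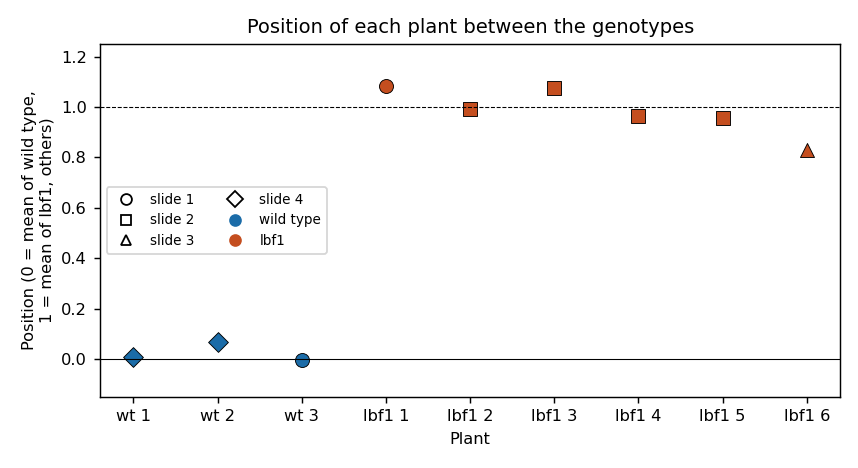
The x axis lists the 9 plants and the y axis gives the position of each between the genotypes (0, mean of the wild type plants; 1, mean of the lbf1 plants; the plant itself left out), with symbols for the 4 slides. Wild type plant 3 and lbf1 plant 1, both on slide 1, sit at -0.0032 and 1.08.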

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

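Of the alternatives here, those with E1A control scaling, plain subtraction, mean pixels, probes found on at least 3 plants or on all wild type arrays, wild type plant 3 alone, the plants outside slide 2, and, for the spread, probes found on all arrays and median centring were chosen after seeing the data. The number of called probes, 14886, moved by less than 1.5 times under 27 of 36 alternatives. Only the number is compared there, not which probes were called. E1A scaling is among the 27 with 19476 called probes, of which 8313 were also called in the main fit. Fewer were called with a replicate block (9372), slide as a block (6342), scan day as a block (8498), within scan day 1 (7762), with wild type plant 3 alone (7483), at an adjusted p under 0.01 (9699), with treat at 1.5-fold (2931), and outside slide 2 with quantile normalisation (6131) or E1A scaling (3253). Most of these use fewer plants or a stricter limit. Counts under E1A scaling carry the limit given above. E1A scaling gave 7216 probes at 2-fold or more, 6592 higher and 624 lower in lbf1, and outside slide 2 it gave 574 lower. Plain subtraction gave 6323 such probes, 2959 higher and 3364 lower. The cause was not tested.

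Leaving out 1 plant at a time gave 11207 to 15014 called probes and 3609 to 4130 at 2-fold or more, of which 1788 to 1989 were higher and 1800 to 2145 lower in lbf1. The probes found in lbf1 only numbered 535 to 964 and those found in wild type only 105 to 139. Leaving out a plant only relaxes the condition for these groups, so their sizes could not fall below 531 and 100. The 4 named probes kept their direction and stayed past the threshold in all alternatives that tested them. These probes were picked on the same arrays for their large differences, so keeping their direction was close to fixed in advance. Their differences ranged from 7.15 to 9.26 for Lus10001042, from 7.27 to 9.22 for Lus10000474, from -5.31 to -3.83 for Lus10022806 and from -5.28 to -3.82 for Lus10011872, with a highest limma adjusted p of 0.0255.

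Shared plant numbers did not pair the plants: deviations from the group means of plants 1, 2 and 3 correlated across probes at 0.018, -0.097 and -0.16, and none correlated best with its own number. The replicate block called 9372 probes, against 12539 in the same 6 plants without it. The spread between arrays averaged 0.042, or 0.059 with median centring and 0.060 with 75th percentile scaling. The spread between plants averaged 0.13, or 0.16 over probes found on all 11 arrays, 0.25 with median centring and 0.26 with 75th percentile scaling. The averages for arrays and for plants rest on unlike numbers of values, so they are not directly comparable. The gene list alternatives were not run, since no probe has a gene name. Low signal limits the 10348 probes found on no array.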

Other observations

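The test of directions on slide 1, those of regrouping and of wild type plant 2, the use of E1A scaling and the filter on wild type arrays were chosen after the results were seen. None of 10 measures over the 6 lbf1 plants had a plant that stood apart by Dixon's test.

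Neighbouring identifiers tended to change together. Among 43336 pairs of Lus probes with consecutive numbers, the log2 differences correlated at 0.099 across pairs, which are not independent replicates, and the highest correlation in 100000 shuffled orders was 0.023 (permutation p of 1e-05, the smallest they can give). In 218 pairs both probes were higher in lbf1 by 2-fold or more, against a mean of 80.4 in shuffled orders, and in 181 pairs both were lower, against 92.0. Pairs with opposite changes numbered 148, against 172. The files do not say how these numbers run along the genome.

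The difference between lbf1 and wild type exceeded what regrouping gives. Only 1 of the 84 splits of the 9 plants into 3 and 6, the real one, reached 14886 called probes, and the highest other split gave 284. For changes of 2-fold or more it was again 1 split of 84, with 3880 probes against 76 in the highest other split. These counts argue against a chance regrouping of plants. They come from the same fit, and 1 of 84 is the smallest share that the splits can give. Slide or scan day as the whole source is argued against by slide 1, where 99.1% of the probes called at 2-fold from the other slides differed in the same direction. With 1 plant of each genotype on that slide, smaller slide effects on single probes stay open. The genotype remains as a hypothesis, and differences in field position or harvest between the genotypes, which the labels do not describe, were not tested.

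Large changes were mostly increases in lbf1, but the size of the excess moved with the scaling. With quantile normalisation 656 probes rose and 300 fell by 4-fold or more, a ratio of 2.19, and the ratio was 1.68 with median centring, 1.98 with 75th percentile scaling and 12.1 with E1A scaling (1249 and 103 probes; 7.03 without the plants of slide 2). Increases thus outnumbered decreases under each of these, which argues against scaling as the whole source, not against its effect on the size. Probes near background in wild type were examined as the source with filters, under quantile normalisation. Among probes found on all 11 arrays the ratio was 1.65, with 418 increases and 253 decreases. Among probes found on all wild type arrays it was 1.39, with 418 increases and 301 decreases. Both filters remove increases from background, and only the first also removes decreases to background in lbf1. Increases still outnumbered decreases under each. Both filters keep probes that were found but dim in wild type, which can rise 4-fold more easily than fall 4-fold. The excess left under the filters therefore does not decide on this source. In a split that was not planned, the ratio was 2.31 above the median of the mean level and 1.76 at or below it. That mean includes the lbf1 plants, so probes that rise from background can lie in the upper set. How much of the excess comes from probes near background thus stays undecided, and a biological source in the genotype stays open.

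Wild type plant 2 held traces of transcripts that were high in lbf1. Among 50 probes found in all lbf1 plants at a mean above 1000 units and not found in wild type plants 1 and 3, 46 were higher in plant 2 than in the other wild type plants, at a median of 0.629% of the lbf1 level (quartiles 0.357% and 1.09%). The same comparison gave 14 of 36 probes for plant 1 and 9 of 44 for plant 3. A higher background on that array is argued against by probes found on no array, whose median excess was -0.023 units, against 12.3 units for the 50 probes. A small admixture of lbf1 RNA may be the source: with the best of 6 donors 14% of the probes lay off one constant ratio, against 9.09% in plant 3 and 2.78% in plant 1. That margin does not decide, so admixture and low expression in plant 2 itself cannot be told apart.

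The closest plants of one group were lbf1 plants 3 and 4, with a median SD of 0.065 over probes found on all arrays, and the next closest pair was lbf1 plants 5 and 6, at 0.10.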
